A study of Mus musculus with 7 samples.

How the data were processed

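RNA was measured in 7 samples of mouse cells, all of the same strain, each on 1 single-colour Affymetrix whole-transcript array. The groups were taken from the sample labels: 1 array of wild-type (WT) embryonic stem cells (ESC), 2 of WT induced pluripotent stem cells (iPSC), 2 of Nanog knockout (KO) iPSC, 1 of WT mouse embryonic fibroblasts (MEF) and 1 of Nanog KO MEF. The labels call the iPSC replicates biological, but whether the 2 KO iPSC arrays are separate lines or cultures of 1 line is unknown. If they are cultures of 1 line, the SE and p-values of KO iPSC do not cover the spread between lines. They name ESC, 2i/LIF and MEF media without saying which sample was grown in which, and they state 73.5 ng of total RNA and 5.5 ug of labelled cDNA for every array. No column of the table belonged to a sample outside these groups (0 unmapped columns).

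The deposited values are intensity values of probe sets on a linear scale, made with Affymetrix Expression Console 1.3.0.187 and RMA per the submitters' processing notes. They ran from 9.67 to 13043, and the distributions of the 7 arrays nearly coincided. The plan written before the data were examined had assumed log2 values. The log2 was therefore taken here, and no further normalization was applied. The scanner files were not part of the material, so background correction and summarization were used as deposited.

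The table holds 33649 probe sets. The platform annotation lists 25335 of them, 23521 with 1 gene symbol and 1814 with several, and does not list 8314, which are unnamed here. Through the Entrez identifier 23328 of the probe sets with 1 symbol matched a current RefSeq gene of the mouse assembly GRCm38.p6, 193 did not, and 0 symbols changed. Genes and chromosomes are named from these tables, and no coordinates are given because the files name no genome build. Probe sets with no symbol or several stayed out of the gene tests. Where a gene had several probe sets (1082 genes), the probe set with the highest mean over the 7 arrays stood for it, which gave 22180 genes. Of the 111 genes named by the rule given here, 14 had several probe sets, and in 5 of them (Myb, Pstpip2, Rasgrp4, Uchl1 and Zfp640) these differed in the sign of the KO minus WT difference in iPSC. No dim gene was left out.

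As a yardstick for background, the 95th percentile of 1394 olfactory and vomeronasal receptor genes was taken on each array. It lay between 6.30 and 6.50 on the log2 scale. Where every array on the dim side of a comparison lay below its yardstick, the fold is given as a lower bound against the mean yardstick of those arrays and written "at least". The log2 differences beside such bounds are the fitted values. No bounds were made for the interaction, and medians of lists are of fitted values. An array has no read depth, and the number of arrays limits the precision.

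Differences were tested per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings), with the Benjamini-Hochberg adjustment over all 22180 genes and a threshold of 0.05 on the adjusted p. All limma tests were two-sided. KO iPSC were compared with the 3 WT pluripotent arrays as 1 group (3 residual degrees of freedom). KO iPSC against WT iPSC, WT ESC against WT iPSC, and the interaction of genotype with cell type came from a fit of all 7 arrays with 1 coefficient per group (2 residual degrees of freedom). In that fit the groups with 1 array have no replicates and are assumed to vary like the iPSC groups. iPSC against MEF, and KO against WT common to both cell types, came from an additive fit of cell type and genotype on 6 arrays (3 residual degrees of freedom). The MEF pair has 1 array per genotype and was given as differences with no test. The p-values measure spread between the samples, and the comparisons share arrays, so no overlap between their gene sets was counted. Numbers written with a plus or minus difference are log2 values, and SE is the standard error of the fit.

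Lists of genes (34 lists, 714 symbols, of which 656 were found among the 22180 genes and 58 were not analysed here) were fixed before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternative settings. A list was tested with limma's camera at a preset correlation of 0.01, adjusted over the 34 lists within a comparison, and again with an estimated correlation. Members past the threshold were counted after adjustment over all genes and also adjusted over the list alone. With an estimated correlation, 0 lists passed in any comparison. That setting also rests on the few residual degrees of freedom of each fit and had little power. A list that failed in it is therefore not shown to be a false call. For the pluripotency network in iPSC against MEF, the estimated correlation was 0.0105, close to the preset value. The unadjusted camera p was still 2.5e-22 at the preset correlation and 0.0024 with the estimated one. Other lists that passed often had higher estimates. In KO iPSC against WT pluripotent they were 0.831 for fibroblast, 0.712 for epithelial junction, 0.393 for G1/S, 0.365 for glycolysis and 0.269 for G2/M. They were 0.145 for primed epiblast, 0.022 for neuroectoderm and -0.012 for germline genes. Where members vary together more than the preset assumes, the p at the preset correlation is too small. For the MEF pair, a list's median was placed among 10000 random lists of the same size matched on mean level.

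For each tested comparison the named genes are the 12 with the largest positive and the 12 with the largest negative log2 difference among genes past the threshold. They had to show no overlap between the arrays of the groups compared, a higher group mean above the median of all genes, and a symbol other than predicted genes, clone names, small RNAs and receptor families. For the MEF pair the 8 largest differences in each direction under the same conditions on level and symbol are named. Members of the fixed lists and Nanog are named besides these.

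The position of an array between WT MEF and WT ESC is the median, over genes at least 4-fold different between those 2 arrays, of the array's distance from WT MEF divided by the distance of WT ESC from WT MEF. The test code was checked on simulated data of the same size, with 100 genes changed by 1 and 100 by 2 on the log2 scale. It recovered 79% and 97% of these for KO iPSC against WT pluripotent, 64% and 99% for KO iPSC against WT iPSC, and 33% and 91% for WT ESC against WT iPSC. It recovered 81% and 98% for iPSC against MEF, 89% and 99% for the genotype difference common to both cell types, and 2% and 67% for the interaction. False calls made up between 1.43% and 4.62% of all calls. The simulated noise was independent between arrays, with the same variance of a gene on every array. In the data the KO iPSC arrays differed less (SD 0.15) than the WT iPSC arrays (SD 0.32). These rates therefore check the code and need not hold for these arrays.

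The alternatives tried were 2 filters on dim genes, the mean of a gene's probe sets, every probe set tested, quantile normalization, median centring, a mean-variance trend with and without robust fitting, an added 2-fold threshold, other groupings of the same arrays, the replicate number as a block, and each array left out in turn. Alternatives chosen after seeing the data left out fibroblast-high genes or X-linked genes, counted the 2 KO iPSC arrays as 1, or set KO iPSC against WT ESC alone. No group has enough arrays for an outlier test. Figures were drawn with matplotlib 3.10.9.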

Results

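Transcript levels were measured on 7 arrays of mouse cells: 1 of WT ESC, 2 of WT iPSC, 2 of Nanog KO iPSC, 1 of WT MEF and 1 of Nanog KO MEF. iPSC are cells brought to an ESC-like state from somatic cells, and MEF are fibroblasts grown from embryos. Nanog is a homeodomain transcription factor of the pluripotency network, and the series sets Nanog KO iPSC against WT pluripotent cells to ask whether cells without Nanog can become iPSC. The median log2 intensity of the arrays lay between 7.05 and 7.13, and 61.0% to 63.7% of genes lay above background. The 2 KO iPSC arrays differed by more than 2-fold in 4 genes (SD of the gene differences 0.15), the 2 WT iPSC arrays in 350 genes (SD 0.32). Groups with 1 array have no replicates, and where such a group stands alone in a test, its spread is assumed to equal that of the iPSC groups.

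Nanog, measured by 1 probe set, stood at a log2 intensity of 12.73 in WT ESC and at 12.84 and 12.76 in the 2 WT iPSC arrays. In the KO iPSC arrays it stood at 7.50 and 7.44, above their background of 6.50 and 6.44. WT MEF gave 6.53 and KO MEF 6.42, close to background. KO iPSC exceeded KO MEF by 1.05, a difference from 1 KO MEF array whose spread was not measured. Whether the probe set lies in the deleted part of the gene is not stated in the labels, so the remaining signal does not show whether an altered transcript was made.

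On a scale from 0 (WT MEF) to 1 (WT ESC), over 1083 genes at least 4-fold different between those 2 arrays, the KO iPSC arrays lay at 0.954 and 0.964 and the WT iPSC arrays at 0.834 and 1.01. KO MEF lay at 0.0183. Over the 591 genes higher in MEF, the KO iPSC arrays both lay at 1.04, and the WT iPSC arrays at 0.788 and 1.03. Over the 492 genes higher in ESC, the KO iPSC arrays lay at 0.750 and 0.762, and the WT iPSC arrays at 0.920 and 0.985. The correlation across genes with WT ESC was 0.965 and 0.966 for KO iPSC, 0.984 and 0.990 for WT iPSC and 0.895 for KO MEF, where genes are not independent replicates. These positions are given as values, with no test. The WT arrays also carried more fibroblast signal, with list medians of 8.61 in WT ESC, 9.85 and 7.91 in WT iPSC, and 7.43 and 7.23 in KO iPSC. Fibroblast RNA in WT ESC, which sets the value 1, would raise the KO iPSC position over genes higher in MEF. The position over all 1083 genes therefore does not show that KO iPSC lay as near to WT ESC as WT iPSC.

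**Figure D1:**
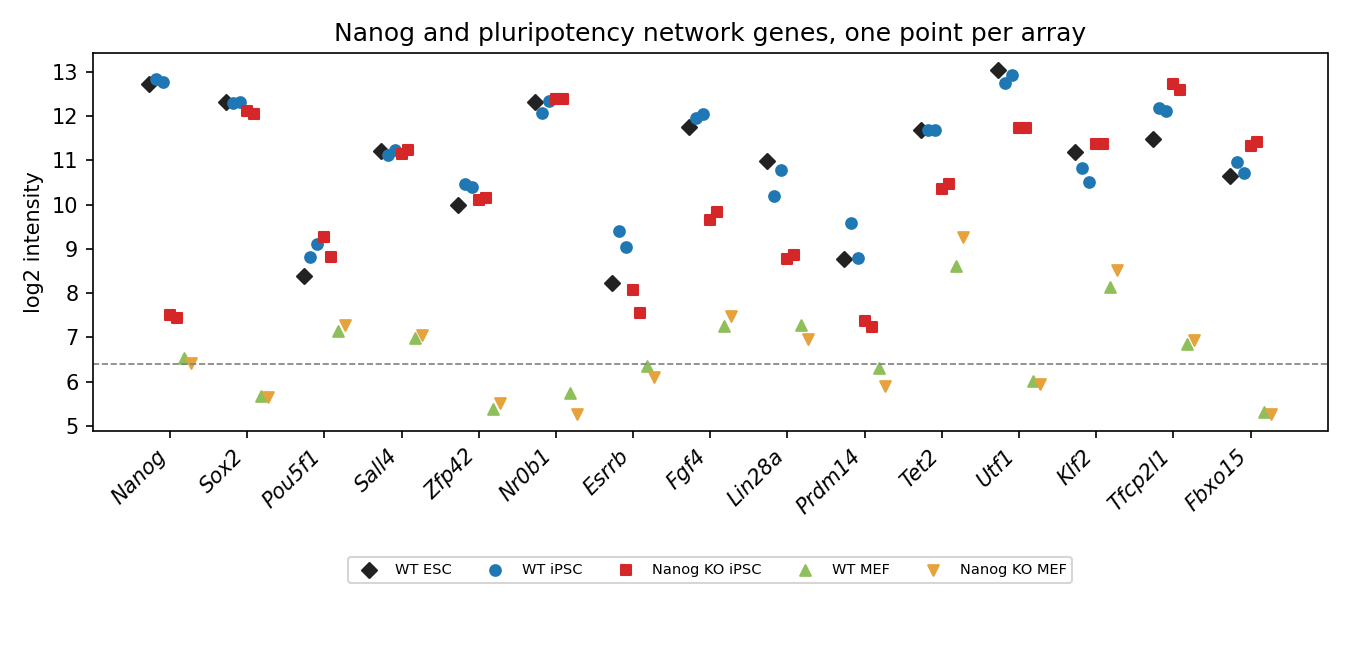
Log2 intensity of Nanog and 14 genes of the pluripotency network, with 1 point per array and the mean background as a dashed line. Nanog stood at 7.50 and 7.44 in the KO iPSC arrays against 12.73 to 12.84 in the WT pluripotent arrays, and Sox2 had group means of 12.09 and 12.31 in KO and WT iPSC.

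The comparison of the 2 KO iPSC arrays with the 3 WT pluripotent arrays addresses the question of the series. Nanog fell 39.4-fold (log2 -5.30, SE 0.08, 2 arrays against 3, adjusted p = 3.6e-05). Of the 39 measured genes of the pluripotency network, 9 fell, 3 rose and 27 did not pass (9 and 5 adjusted over the list alone). The growth factor Fgf4 fell 4.54-fold (log2 -2.18, SE 0.12), the RNA-binding protein Lin28a 3.61-fold (-1.85, SE 0.23), the chromatin regulator Prdm14 3.36-fold (-1.75, SE 0.27) and the cytosine dioxygenase Tet2 2.43-fold (-1.28, SE 0.08). Stat3 (0.65), Fbxo15 (0.61) and Rif1 (0.39) rose, while the core factors Sox2 (-0.22, SE 0.08) and Pou5f1 (0.27, SE 0.24), and also Nr0b1 (0.14) and Zfp42 (-0.16), did not pass. The list as a whole had a median of -0.0043 and an adjusted p of 0.323. Of 20 naive pluripotency genes, several of them shared with that list, 5 fell and 1 rose, with a median of 0.06 and a mean of -0.28.

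Genes of mitosis fell together: 16 of 24 members of the cell cycle G2/M list fell and 0 rose (20 fell adjusted over the list alone). They included Cenpf (-1.08), the microtubule-binding Nusap1 (-1.04), the checkpoint kinase Bub1b (-0.99) and the anaphase activator Cdc20 (-0.82), and the list median was -0.56. Of 28 G1/S genes 5 fell and 0 rose (9 fell and 2 rose adjusted over the list alone), among them the ribonucleotide reductase subunit Rrm2 (-1.01) and cyclin Ccne1 (-0.86). The adjusted p was 5.13e-11 for G2/M and 0.000327 for G1/S. With an estimated correlation the adjusted p = 0.738 for G2/M and 0.893 for G1/S, so neither passed in that setting of little power.

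Glycolysis and germline genes were lower as well. Of 19 glycolysis genes 7 fell and 0 rose (10 fell adjusted over the list alone): the HIF prolyl hydroxylase Egln3 (-3.81), the lactate transporter Slc16a3 (-1.75), lactate dehydrogenase Ldha (-1.40) and Pfkl (-1.12) were the 4 with the largest differences. Of 25 germline and meiosis genes 8 fell and 0 rose (9 fell adjusted over the list alone), among them the receptor kinase Kit (-2.52), the piRNA factor Mael (-2.40) and the RNA-binding Dazl (-1.62). The adjusted p was 5.67e-05 for glycolysis and 6.11e-05 for germline genes. It became adjusted p = 0.893 and adjusted p = 0.505 with an estimated correlation.

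Primed epiblast genes also fell, 6 of 20 with 0 rising (10 fell and 1 rose adjusted over the list alone). They were the tight junction gene Cldn6 (-2.59), the Nodal antagonist Lefty1 (-2.56), the transcription factor Otx2 (at least 4.12-fold), Sox4 (-1.35), Igfbp3 (-1.23) and Sfrp2 (-0.72). Of 16 neuroectoderm genes 4 fell and 0 rose (6 fell and 1 rose adjusted over the list alone), with Olig2 (at least 11.4-fold), the neuronal tubulin Tubb3 (-3.30) and the adhesion molecule Ncam1 (-2.99) ahead. Of 19 epithelial junction genes 5 fell and 1 rose (7 and 2 adjusted over the list alone), among them the splicing factor Esrp1 (at least 2.76-fold) and the adhesion molecule Epcam (-1.48). The adjusted p values were 0.000301, 0.0106 and 0.0392 in that order. With an estimated correlation they were adjusted p = 0.893, adjusted p = 0.738 and adjusted p = 0.967.

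Fibroblast genes were lower in KO iPSC than in the WT pluripotent arrays. Of 37 fibroblast genes 10 fell and 0 rose (13 fell adjusted over the list alone). Among them were the matrix proteoglycan Bgn (-5.08, SE 0.63), the collagen cross-linking enzyme Lox (at least 11.4-fold, fitted log2 -4.26, SE 0.99), smooth muscle actin Acta2 (-4.14, SE 0.29) and Thbs1 (-3.16). Another bright probe set of Bgn gave -1.42 in KO minus WT iPSC, against -4.93 for the one used, so the size for Bgn is uncertain. For the fibroblast list the adjusted p was 7.35e-05, and adjusted p = 0.967 with an estimated correlation. The median log2 level of the list was 9.85 and 7.91 in the 2 WT iPSC arrays, 8.61 in WT ESC, 7.43 and 7.23 in the KO iPSC arrays, and 11.9 and 12.2 in the MEF arrays. Both MEF arrays lay above each WT pluripotent array in 10 of these 10 genes, but in 0 of the 16 G2/M genes and 1 of the 8 germline genes that fell. Among the members of other lists named in this comparison, Sox4, Ncam1 and Ier3, which fell, also had both MEF arrays above each WT pluripotent array.

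**Figure D2:**
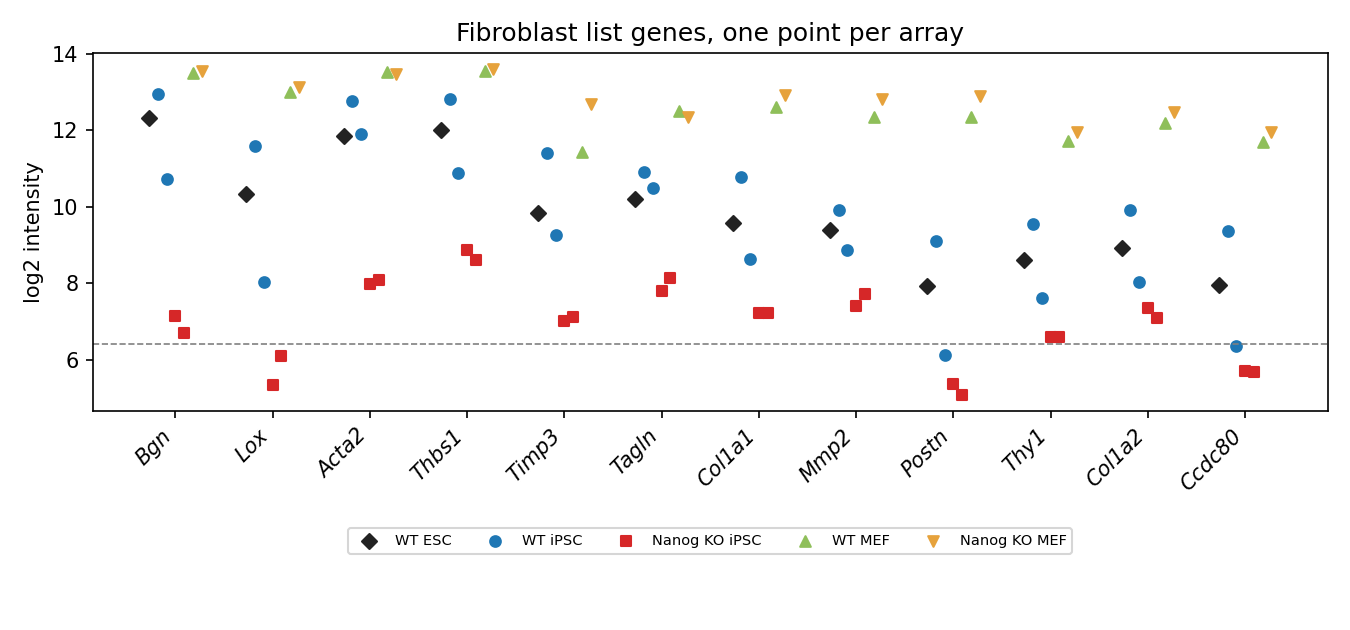
Log2 intensity of 12 fibroblast genes, with 1 point per array and the mean background as a dashed line. The list median was 9.85 in WT iPSC 1, 8.61 in WT ESC and 7.91 in WT iPSC 2, and 7.43 and 7.23 in the KO iPSC arrays.

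Among signalling targets, members moved in both directions. Of 20 MAPK/ERK targets 7 rose and 3 fell (9 and 5 adjusted over the list alone). The immediate early genes Egr1 (3.04, SE 0.49) and Egr2 (2.36), and Phlda1 (2.16) and the ERK phosphatase Dusp5 (1.55), rose, while cyclin Ccnd1 (-1.56), Ier3 (-1.30) and Etv5 (-0.40) fell. Of 16 Wnt targets 7 rose and 1 fell (7 and 3 adjusted over the list alone): the Wnt antagonists Apcdd1 (2.02) and Axin2 (1.22) and the transcription factor Sp5 (0.85) rose and Ccnd1 fell. Neither list passed (adjusted p = 0.229 and adjusted p = 0.185).

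Outside the lists, the ATP-gated channel P2rx7 rose 21.7-fold (4.44, SE 0.15), Nckap1l by 3.32 and the neurofilament gene Nefl 8.65-fold (3.11). Several genes rose from below background in all 3 WT arrays, namely Pramel30, a member of a multi-copy family, by at least 10.1-fold, the mitochondrial enzyme Dmgdh at least 10.5-fold, the aldehyde oxidase Aox3 at least 8.36-fold, the transcription factor Tfap2a at least 11.6-fold and the tryptophan-degrading Ido2 at least 10.5-fold. So did Pramel14 (at least 4.02-fold), Adh1 (at least 6.28-fold) and Nefm (at least 5.33-fold), and Adgrg6 rose by 3.49. The purine salvage gene Hprt fell below background, by at least 20.8-fold (fitted log2 -6.28, SE 0.19). The E3 ligase Rlim fell 16.0-fold (-4.00, SE 0.11), the cyclin Ccnd2 at least 11.8-fold, Ifitm3 14.4-fold (-3.85) and Pla2g1b 14.3-fold (-3.84). Rps13 (-4.31) and the protease inhibitor Timp2 (at least 10.8-fold) fell as well. Timp2 and Ccnd2, like the fibroblast genes, had both MEF arrays above each WT pluripotent array. Rps13 has many pseudogene copies, and the specificity of its probe set was not tested. Hprt, Bgn and Rlim are X-linked, and X-linked genes as a whole were lower, with a median difference of -0.21 over 445 expressed genes against -0.05 to 0.02 on the autosomes.

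In limma, 1529 genes were higher and 1954 lower, 15.7% of the 22180 tested, and 370 and 619 of these differed at least 2-fold. The counts depended on the arrays used: 157 and 184 genes passed without KO iPSC replicate 1, 173 and 230 without KO iPSC replicate 2, 159 and 206 with both KO arrays counted as 1, and 947 and 1283 without WT iPSC replicate 2, while 1729 and 2438 passed without WT iPSC replicate 1 and 1538 and 2118 without WT ESC. The balance depended on the scaling, since higher genes made up 43.9% of the calls as deposited and 54.1% after each array was centred on its median.

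**Figure D3:**
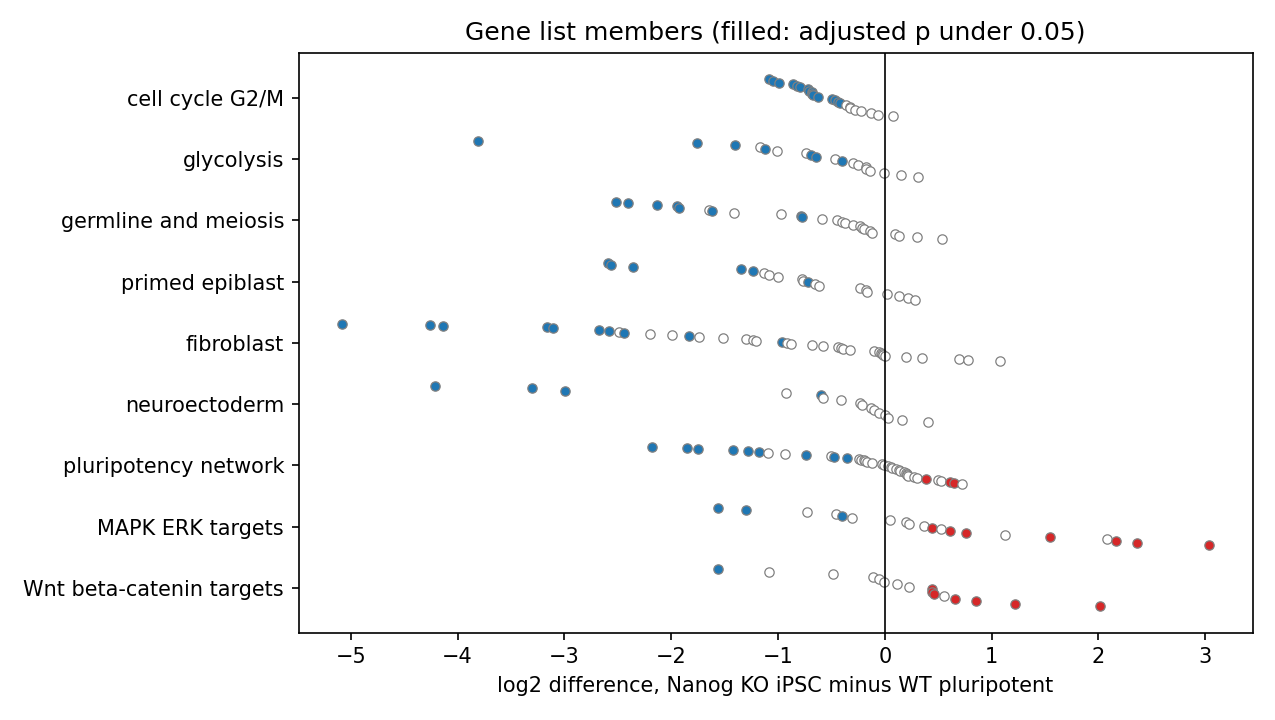
Log2 difference of KO iPSC minus WT pluripotent for each member of 9 gene lists, with filled points for an adjusted p under 0.05. In the cell cycle G2/M list 16 of 24 members fell and 0 rose, and in the Wnt target list 7 of 16 rose and 1 fell.

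Within iPSC, the genotypes were compared with the cell type held the same, on the KO arrays of the preceding comparison. The medium of each array is not stated. A difference in medium between the genotypes, here or in that comparison, cannot be told apart from loss of Nanog. Nanog fell 40.1-fold (-5.32, SE 0.09, 2 arrays against 2, adjusted p = 0.00041). In the pluripotency network 9 of 39 genes fell and 4 rose (12 and 6 adjusted over the list alone), and here the orphan receptor Esrrb fell (-1.43) while the naive factors Klf2 (0.70) and Tfcp2l1 (0.50) rose. Fgf4 (-2.27), Prdm14 (-1.89) and Lin28a (-1.68) fell. Of the 20 MAPK/ERK targets 9 rose and 4 fell (10 and 5 adjusted over the list alone), with Egr1 (3.38, SE 0.43), Fos (2.77) and Egr2 (2.61) ahead, and the list did not pass (adjusted p = 0.148).

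In the same lists as before, G2/M genes fell in 16 of 24 cases (20 adjusted over the list alone), germline genes in 11 of 25 (12), glycolysis genes in 7 of 19 (10), primed epiblast genes in 8 of 20 (9), fibroblast genes in 9 of 37 (9) and G1/S genes in 5 of 28 (6), and 0 rose in each. The adjusted p values were 3.65e-09, 2.32e-06, 0.000386, 0.000648, 0.000287 and 0.000936. Of the neuroectoderm genes 5 of 16 fell and 1 rose, 5 and 1 also adjusted over the list alone (adjusted p = 0.0424). For each of these lists adjusted p = 0.968 with an estimated correlation. Germline genes that fell here included Rhox5 (-1.56), Ddx4 (at least 1.72-fold) and Mov10l1 (at least 1.86-fold). The immediate early gene Fosb rose by 3.56, and the X-linked Usp26 fell by 3.87 on the log2 scale and Eprn at least 5.99-fold. The other named genes were shared with the comparison against all WT pluripotent arrays.

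X-linked genes shifted as a class. The median over 445 expressed X-linked genes was -0.32 in KO iPSC minus WT iPSC, against -0.04 to 0.03 on the autosomes, and 73.7% of them lay below 0. WT ESC minus WT iPSC gave -0.30, and KO iPSC minus WT ESC 0.03.

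**Figure D4:**
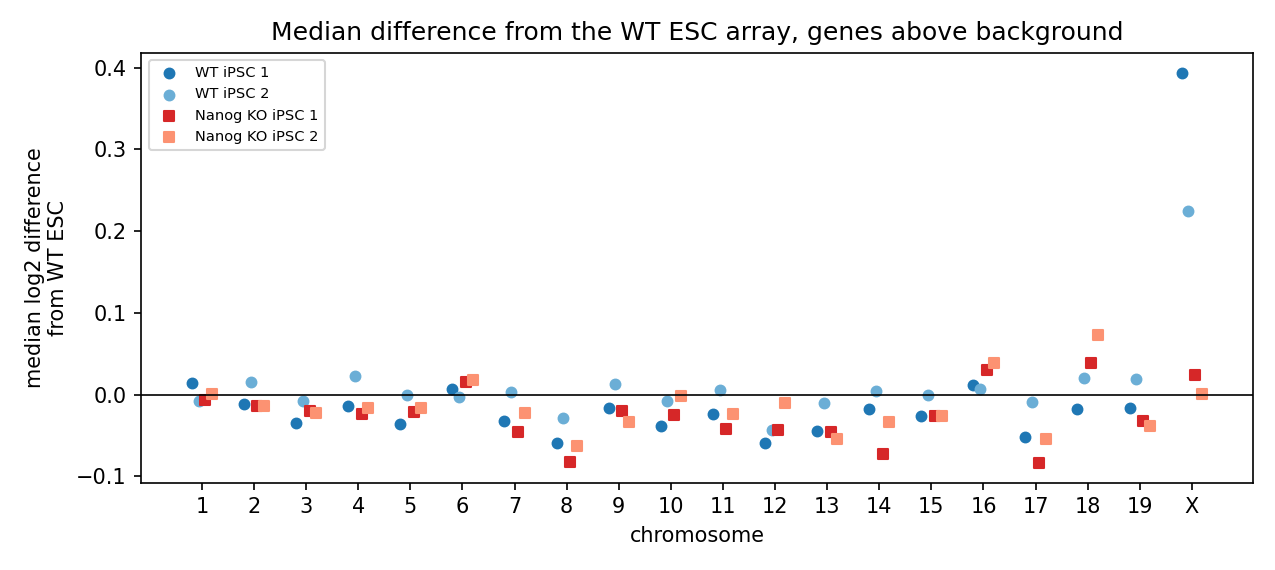
Median log2 difference from the WT ESC array over the expressed genes of each chromosome, for the 4 iPSC arrays. The X chromosome stood at 0.39 and 0.23 in the WT iPSC arrays and at 0.02 and 0.00 in the KO iPSC arrays.

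In limma 1538 genes were higher and 2118 lower in KO than in WT iPSC, 390 and 655 of them at least 2-fold. The excess of lower genes depended on the scaling, with 1859 higher and 1795 lower after median centring and 1864 and 1854 after quantile normalization. With an iPSC array left out, only the other iPSC pair sets the spread of this fit. The KO pair differed less (SD 0.15) than the WT pair (SD 0.32), and counts were higher where the KO pair was left. The same holds for WT ESC against WT iPSC and for the interaction. Without KO iPSC replicate 1 the counts were 212 and 307, without KO iPSC replicate 2 219 and 349, without WT iPSC replicate 1 2504 and 3475, and without WT iPSC replicate 2 2457 and 3157.

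WT ESC and WT iPSC were compared to measure how far the WT pluripotent cells differed from each other. The interferon-induced Oasl2 was at least 5.76-fold higher in WT ESC (fitted log2 3.01, SE 0.11, 1 array against 2), and the germline genes Ddx4 (1.82), Ybx2 (1.56) and Mov10l1 (1.32) and the transcription factor Myb (1.77) rose as well. The germline list as a whole did not pass (median -0.13, 5 higher and 3 lower of 25 adjusted over the list alone, adjusted p = 0.862). Pstpip2 (2.00), Slc38a3 (1.87), Tarm1 (1.84), Atp10a (1.70), Zfp493 (1.66), Irgm2 (at least 2.15-fold) and Rasgrp4 (1.42) also passed as higher in WT ESC. The imprinted gene Mest fell 14.6-fold (-3.87, SE 0.32) relative to WT iPSC, and 5 X-linked genes fell, Nxf3 (at least 5.87-fold), Usp26 (-3.33), Efhc2 (at least 4.94-fold), Fthl17b (-2.66) of a multi-copy family, and Nup62cl (-2.18). Slc13a5 (-2.97), the neprilysin gene Mme (-2.39), Eprn (-2.35), Slc1a1 (-2.30), Cyp2b23 (at least 4.02-fold) and Xaf1 (-1.93) fell too. Nanog did not differ by more than its error (-0.07, SE 0.11).

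Lists passed here with few or no members past the threshold over all genes. The p53 and senescence list was lower in WT ESC (median -0.47, 0 of 18 members over all genes, 7 adjusted over the list alone, adjusted p = 4.3e-08), with Plk2 at -1.40 and Perp at -1.05. Epithelial junction genes (median 0.36, 3 of 19 higher adjusted over the list alone, adjusted p = 8.98e-06), primed epiblast genes (0.38, 5 of 20, adjusted p = 0.000787), amino acid stress genes (0.32, 0 of 24, adjusted p = 0.000241) and glycolysis genes (0.26, 0 of 19, adjusted p = 0.00258) were higher. The two-cell-like list was lower (median -0.64, 0 of 16, adjusted p = 0.0003). For all 6 adjusted p = 0.779 with an estimated correlation. The fibroblast list had a median of -0.17 and an adjusted p of 0.161.

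In limma 18 genes were higher and 18 lower in WT ESC, and 2704 had an unadjusted p under 0.05. The counts were 37 and 58 with a trend and robust fitting, 9 and 13 without the lowest 0.333 of genes and 0 and 3 without the lowest 0.5 (1721 with an unadjusted p under 0.05). They were 488 and 407 without WT iPSC replicate 1, 1095 and 1194 without WT iPSC replicate 2, and 0 and 1 without either KO iPSC replicate, where 1641 genes had an unadjusted p under 0.05.

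iPSC were compared with MEF, with genotype as a covariate, to describe the difference between the cell types. Pluripotency genes rose and fibroblast genes fell. The Nodal co-receptor Tdgf1 was at least 74.7-fold higher in iPSC (fitted log2 7.24, SE 0.17, 4 arrays against 2), Nr0b1 at least 59.4-fold (6.79), Sox2 at least 55.6-fold (6.53, SE 0.09), Utf1 at least 59.0-fold (6.31) and Dppa2 at least 45.5-fold (5.86). The matrix genes Postn (-6.21, SE 1.02), Ogn (-5.77) and Col12a1 (-5.46) fell, and Aspn fell at least 29.6-fold. Nanog itself, with KO arrays on both sides, did not pass (3.66, SE 1.14, adjusted p = 0.065). Other genes that rose were Zfp640, Zfp981, Zfp936 and Zscan4e of multi-copy families, Rex2, Fbxo15 and Triml1, by lower bounds of 19.7-fold to 49.7-fold. Adamts5 fell at least 21.7-fold, and Lox, Tgfb3, Ccdc80, Thbs2, S1pr3, Fbln5 and the cytokine receptor Osmr fell, from -5.30 to -4.95. These values pool both genotypes, which can differ. Lox averaged 9.81 in WT iPSC and 5.73 in KO iPSC, and stood at 13.00 in WT MEF and 13.14 in KO MEF.

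Of the pluripotency network 35 of 39 genes rose and 1, Stat3 (-0.48), fell (37 and 1 adjusted over the list alone), and of the fibroblast list 31 of 37 fell and 0 rose (35 adjusted over the list alone). G1/S genes rose in 27 of 28 cases, G2/M genes in 23 of 24, epithelial junction genes such as Cdh1 (4.61) and Epcam (at least 11.2-fold) in 15 of 19, Polycomb genes in 15 of 22 and DNA methylation genes such as Dnmt3l (at least 23.3-fold) and Tet1 (4.48) in 8 of 12. Of 28 Hox genes, which encode positional identity, 23 fell and 0 rose, with Hoxc8 at -3.32. Adjusted over the list alone the counts were 27, 24, 16, 15 and 9 rising and 25 falling. The adjusted p was 8.53e-21 for the pluripotency network, 1.17e-13 for fibroblast genes, 3.85e-12 for G1/S, 5.97e-11 for G2/M, 5.68e-07 for epithelial junction, 0.000108 for Polycomb, 0.00134 for DNA methylation and 4.39e-12 for Hox genes. With an estimated correlation none of the 16 lists that passed did so again, and the smallest adjusted p = 0.0791.

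In limma 3540 genes were higher in iPSC and 3262 lower. Without KO iPSC replicate 1 the counts were 2338 and 2206, and without KO iPSC replicate 2 they were 2250 and 2155.

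The genotype difference common to iPSC and MEF was tested to use the MEF pair beside the iPSC arrays. Nanog lay close to background in both MEF arrays (6.53 in WT and 6.42 in KO), which also differed in Y-linked genes and Xist. A difference shared by both cell types therefore cannot separate loss of Nanog from other differences between the KO and WT cells. Hprt fell at least 18.2-fold (fitted log2 -5.66, SE 0.48, 3 arrays against 3, adjusted p = 0.048), from 10.98, 10.95 and 9.90 in the WT arrays to 4.32, 4.83 and 5.72, each below background. Adh1, an alcohol dehydrogenase, rose at least 7.65-fold (fitted log2 3.66, SE 0.24), and the complement regulator Cd55 (2.19), Uap1l1 (2.40), Hebp1 (2.04), Dpp7 (1.91), Serpinb8 (1.88), Tmem202 (1.80) and the anticoagulant Pros1 (1.77) rose. Uchl1 (-2.04), the replication genes E2f8 (-1.62), Rrm2 (-1.18), Cdca7 (-1.16) and Tipin (-1.11), and the kinase Stk26 (-1.46) fell. Nanog did not pass (-3.59, SE 1.07, adjusted p = 0.18). Fuca2, Aldh1l1, Asxl3 and Idua rose by 1.51 to 1.67, and Klk8, Eri2, Tpm2, Adam19 and Crybg3 fell, from -1.32 to -1.10.

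Of 24 G2/M genes 4 fell, Bub1b (-1.06), Cdc20 (-0.99), Cenpf (-0.92) and Nusap1 (-0.91), and 0 rose (21 fell adjusted over the list alone), and of 28 G1/S genes 1 fell (4 adjusted over the list alone). The adjusted p was 5.25e-16 for G2/M and 1.36e-09 for G1/S. Glycolysis genes (median -0.33, 0 of 19 over all genes, 7 lower adjusted over the list alone, adjusted p = 1.37e-05), germline genes (-0.36, 0 of 25, 1 lower, adjusted p = 0.000271), neuroectoderm genes (-0.26, 0 of 16, 2 lower, adjusted p = 0.0475) and fibroblast genes (-0.56, 0 of 37, 0 adjusted over the list alone, adjusted p = 0.0417) were lower as lists. In the MEF pair germline genes had a median of -0.03 (percentile 50.4 of random lists) and fibroblast genes were higher (0.24, 27 of 37). These 2 calls were therefore not shared by MEF. Without WT iPSC replicate 1 the camera direction of the fibroblast list, which is relative to the other genes, reversed, while its median stayed negative. The p53 list (0.28, 0 of 18, 1 higher, adjusted p = 0.0417) and the Wnt list (0.28, 1 of 16, Axin2 at 1.21, 2 higher and 1 lower, adjusted p = 0.0447) were higher. With an estimated correlation the smallest adjusted p = 0.663.

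In limma 50 genes were higher and 45 lower, with 9 and 5 when every probe set was tested, 41 and 24 with a trend, 76 and 57 after quantile normalization and 75 and 70 without the lowest 0.5 of genes. Without any 1 of the 4 iPSC arrays 0 genes were higher and at most 1 was lower, while 2168 to 3092 had an unadjusted p under 0.05.

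The interaction of genotype with cell type asks whether the KO difference in iPSC departed from that in MEF. The MEF side rests on 1 array of each genotype, and these differed in Y-linked genes, in Xist and in macrophage genes as well. The urokinase receptor Plaur gave the largest positive value, 4.63 (SE 0.18): it stood at 11.46 and 11.48 in KO iPSC and averaged 8.9 in WT iPSC, and it stood at 9.1 in KO and 11.2 in WT MEF. The ERK target Phlda1 (3.66) and the ERK phosphatase Dusp5 (3.52) had the same pattern, and P2rx7, Pramel30, Dmgdh and Aox3 were higher in KO iPSC with little difference in MEF. Serpina3n (-6.85), the Wnt receptor partner Lgr5 (-6.32) and the matrix proteoglycans Lum (-5.54) and Dcn (-5.12) were higher in KO MEF than in WT MEF or any iPSC group. Nanog gave -5.22 (SE 0.15, adjusted p = 0.0034). These are fitted values, and where a group lay below background their size rests partly on values under it.

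By list, G1/S genes were higher in the interaction (8 of 28 rose, 15 adjusted over the list alone, median 0.56, adjusted p = 6.66e-07), as were G2/M genes (5 of 24, 15 adjusted over the list alone, 0.65, adjusted p = 1.09e-06) such as Cenpe (1.70) and Kif11 (1.24). The G2/M median was -1.16 in KO minus WT MEF and -0.52 in KO minus WT iPSC. Macrophage genes (2 of 14, 4 adjusted over the list alone, 0.61, adjusted p = 0.000949) were higher as well. Fibroblast genes (4 of 37 fell, 4 adjusted over the list alone, median -1.59, adjusted p = 7.31e-06), interferon genes (4 of 24, 8 adjusted over the list alone, -0.45, adjusted p = 9.22e-05) such as Oasl2 (-2.08), and germline genes (8 of 25, 8 lower and 1 higher adjusted over the list alone, -0.44, adjusted p = 0.000704) were lower. Primed epiblast genes (6 of 20, 6 adjusted over the list alone, -0.48, adjusted p = 0.00292) and neural crest genes (4 fell and 1 rose of 10, 5 and 1 adjusted over the list alone, -0.89, adjusted p = 0.02) were lower too. With an estimated correlation the smallest adjusted p = 0.749. In limma 682 genes were higher and 1215 lower. Without KO iPSC replicate 1 the counts were 19 and 70, without KO iPSC replicate 2 they were 40 and 118, without WT iPSC replicate 1 2084 and 2932, and without WT iPSC replicate 2 2036 and 2801.

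The MEF pair has 1 array of each genotype and no test. The 2 arrays also differed in sex-linked genes: Eif2s3y and Uty stood at 9.21 and 8.78 in KO MEF and at 5.05 and 4.86, below background, in WT MEF, and Xist at 9.15 and 11.97. Both Y-linked genes lay below background in each KO iPSC array, so the KO MEF array does not match the KO iPSC in them. The labels do not say that the iPSC came from these MEF. KO MEF exceeded WT MEF in Lgr5 (at least 61.0-fold, log2 6.30), the protease inhibitor Serpina3n (at least 46.3-fold, 6.14), Lum (at least 17.7-fold), Egfl6 (5.22), Agtr2 (at least 15.3-fold), the matrix gene Dpt (at least 24.4-fold), Arhgap20 (at least 22.9-fold) and Olfml1 (at least 7.51-fold). The potassium channel genes Kcnma1 (-4.79) and Kcnmb1 (-2.84), Hprt (at least 11.7-fold), Lce1h (-3.76), Cdh10 (at least 10.1-fold), Map3k7cl (-3.04), the chemokine Ppbp (-2.84) and Xist (-2.82) were lower. G2/M genes were lower in KO MEF in all 24 cases, 17 of them at least 2-fold (median -1.16), and G1/S genes had a median of -0.84, each below all of 10000 random lists (percentile 0). Interferon genes (median 0.30) and fibroblast genes (0.24) lay at percentile 100, neural crest genes (0.49) at 99.98, p53 genes (0.26) at 99.62, Y-linked genes (0.29) at 99.59, primitive endoderm genes (0.14) at 98.25 and the pluripotency network (0.08) at 97.74. Macrophage genes (-0.68) lay at percentile 0, glycolysis genes (-0.31) at 0.11 and Hox genes (-0.17) at 1.1. Members of a list can vary together, unlike genes drawn at random, and the spread between MEF cultures was not measured. These percentiles are therefore not p-values. Altogether 620 genes were at least 2-fold higher and 392 at least 2-fold lower in KO MEF.

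Among the 1538 genes higher in KO than WT iPSC, 60.4% were also higher in KO MEF, and among the 2118 lower genes 58.5% were lower in KO MEF, against 46.4% higher and 53.6% lower over all genes. The iPSC and MEF arrays are separate samples, and genes are not independent replicates. A shared direction does not separate loss of Nanog from other differences between the KO and WT cells.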

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

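The tests of fibroblast RNA, of the X chromosome and of Hprt in this part were chosen only after the results were seen, and the interaction and its lists were planned.

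Genes abundant in MEF stood above the KO iPSC level in the WT pluripotent arrays, and fibroblast RNA in those arrays, from feeder cells or cells left unchanged, is a candidate explanation. Of 47 genes abundant in both MEF arrays and low in both KO iPSC arrays, 37 (78.7%) shared the same order of the WT arrays. From high to low it was WT iPSC 1, WT ESC, WT iPSC 2, against 16.7% by chance and 15.4% of all genes. A single source of RNA would give a shared order, but these genes are not independent of each other. The implied median shares were 19.6%, 7.61% and 3.16% in that order. Their quartiles ran from 14.7% to 30.6%, from 4.81% to 14.0% and from 0.892% to 8.07%. The shares thus varied between genes, where a source just like the MEF arrays would give the same share within an array. For most of the lower genes, fibroblast RNA at the levels of the MEF arrays was excluded. In 1137 of the 1954 genes lower in KO iPSC (58.2%), both MEF arrays lay below each WT pluripotent array. Such RNA would have lowered the WT value of these genes. They included 16 of 16 G2/M, 7 of 8 germline and 6 of 7 glycolysis genes that fell. Feeder cells with other levels were not measured. For the 440 lower genes with both MEF arrays above each WT array, fibroblast RNA and lower expression in KO cells cannot be told apart: 70.5% of them would need a share in WT iPSC 2 above 18.0%, the 95th percentile of the abundant genes, but feeder cells need not match the MEF arrays gene by gene. The loss of Nanog stays open as a biological explanation, since the fibroblast signal and the genotype go together in these arrays.

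X-linked genes were lower in KO iPSC than in WT iPSC (median -0.32 over 445 genes, autosomes -0.04 to 0.03), and more active X chromosomes in the WT iPSC may account for it. Relative to WT ESC, the X median was 0.39 and 0.23 in the WT iPSC arrays (lowest value 0.225), above every autosome, and 0.02 and 0.00 in the KO iPSC arrays, within the range of the autosomes. Fibroblast RNA at the levels of the MEF arrays was excluded. Over 150 X-linked genes with both MEF arrays below WT ESC and both KO iPSC arrays, the median was -0.375. The autosomes gave -0.07 to 0.05. Loss of Nanog and a difference in X dosage between lines cannot be told apart, because KO iPSC minus WT ESC gave 0.026 on the X chromosome but rests on 1 WT ESC array. The labels do not give the sex of the lines, so no further explanation was tested.

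Hprt lay below background in all 3 KO arrays, KO MEF included (highest value 5.72), and between 9.90 and 10.98 in the 4 WT arrays. An Hprt allele carried by the knockout line, independent of Nanog, is a candidate explanation and has the values it needs. Loss of Nanog and such an allele cannot be told apart, neither in iPSC, where Hprt was at least 22.6-fold lower (fitted log2 -6.39), nor in MEF, where Nanog lay close to background in both single arrays (WT MEF minus KO MEF 0.11) and loss of Nanog before the MEF were derived was not measured. A deletion that also spans the nearest expressed neighbours was excluded, since Phf6 and Fam122b, chosen after their values were seen, were lower in KO than in WT iPSC (-1.42 and -0.97) but lay at least 1.52 above background in each KO array.

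The difference between KO and WT departed between iPSC and MEF in 682 genes upward and 1215 downward, by the test of the interaction, but in as few as 19 and 70 without KO iPSC replicate 1, and the MEF side is 1 array of each genotype that also differ in Y-linked genes and Xist. Positive values were found for Plaur (4.63), Pramel30 (4.53), P2rx7 (4.15), Dmgdh (4.07), Nckap1l (3.86), Ctnnd2 (3.84), Aox3 (3.82), Cd24a (3.74), Phlda1 (3.66), Plagl1 (3.59), Dusp5 (3.52) and Ido2 (3.49). Negative values were found for Serpina3n (-6.85), Egfl6 (-6.46), Lgr5 (-6.32), Lum (-5.54), Igfbp3 (-5.36), Nanog (-5.22), Dhdh (-5.20), Dcn (-5.12), Dpt (-4.92), Agtr2 (-4.89), Apod (-4.72) and Ccnd2 (-4.63). These are fitted values, and where a group lay below background their size rests partly on values under it. By list, the median interaction was 0.56 for G1/S, 0.65 for G2/M, 0.61 for macrophage, -0.48 for primed epiblast, -0.44 for germline, -1.59 for fibroblast, -0.45 for interferon and -0.89 for neural crest genes, and none of these lists passed with an estimated correlation (smallest adjusted p = 0.749).

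Probe sets with no gene symbol or several, which the comparisons of genes leave out, also carried a difference between KO iPSC and WT pluripotent arrays. Of 10128 such probe sets 443 were higher and 320 lower in limma, 58 and 148 of them at least 2-fold.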

How the results depend on the processing

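Nanog fell in KO iPSC against WT pluripotent under every alternative, and its difference was smallest, -5.22, after quantile normalization. Over the alternatives run for each, the named genes kept direction and side of the threshold in 2127 cases, lost the call in 263, gained it in 9 and reversed in 0. A change of direction in a gene not past the threshold in the results above was counted as kept. Some alternatives could not change a fit, such as leaving out a MEF array in KO against WT iPSC, and count as kept too. The named genes were also chosen for large differences, so these counts do not measure the stability of other genes. Lists were run only with an estimated correlation, without the lowest 0.333 of genes, after quantile normalization and without each iPSC array. Their counts in the same order were 295, 75, 0 and 1. The list that reversed was fibroblast in the genotype difference common to iPSC and MEF, whose camera direction turned without WT iPSC replicate 1. Its median with each iPSC array left out ran from -0.89 to -0.10. With an estimated correlation 0 lists passed in any comparison.

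With an added 2-fold threshold, which can only lower a count, 370 genes were higher and 619 lower in KO iPSC against WT pluripotent, 390 and 655 against WT iPSC, 1407 and 1741 in iPSC against MEF, and 32 and 24 in the common genotype difference. With the KO iPSC arrays counted as 1, chosen after seeing the data, 159 and 206 passed against WT pluripotent. For WT ESC against WT iPSC, 9 genes were higher without the lowest 0.333 of genes by mean, 0 were higher and 3 lower in limma without the lowest 0.5 of genes (1721 with an unadjusted p under 0.05), and 37 and 58 passed with a trend and robust fitting. For the common genotype difference, 70 genes were lower without the lowest 0.5 of genes, 9 were higher and 5 lower with every probe set tested, 76 were higher after quantile normalization and 24 were lower with a trend. The position of the KO iPSC arrays was 0.875 and 0.885 over genes at least 2-fold different and 0.962 and 0.977 over genes at least 8-fold different. Apart from the 2-fold threshold, the cause was not tested.

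With 1 array left out in turn, the lone array of a group being assumed to vary like the others, counts of higher and lower genes ran from 157 to 1729 and from 184 to 2438 in KO iPSC against WT pluripotent, and from 212 to 2504 and from 307 to 3475 against WT iPSC. They ran from 0 to 1095 and from 1 to 1194 in WT ESC against WT iPSC (1641 with an unadjusted p under 0.05 at the lowest), and from 2250 to 4004 and from 2155 to 3963 in iPSC against MEF. They ran from 0 to 1538 and from 0 to 2118 in the common genotype difference, and from 19 to 2084 and from 70 to 2932 in the interaction. In the common difference at least 2168 genes had an unadjusted p under 0.05 in limma, and leaving out either MEF array makes that fit the comparison of KO with WT iPSC.

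Pairing the iPSC arrays by replicate number as a block gave 1331 and 1948 genes, but the numbers did not pair the arrays (correlation of the deviations across genes 0.017). Leaving out the 1892 fibroblast-high genes, chosen after seeing the data, gave 1512 and 1763 genes against WT pluripotent and 1641 and 2016 against WT iPSC. Leaving out X-linked genes, chosen likewise, gave 1542 and 1908, and 1509 and 1938. KO iPSC against WT ESC alone, also chosen after seeing the data, gave 1183 and 1770. Signal over background limits the folds of genes below the yardstick, which are lower bounds, and 61.0% to 63.7% of genes lay above it on each array.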

Other observations

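The lists of this part and their tests were planned, and the comparison of fallen genes with the MEF arrays was chosen only after the results were seen.

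Imprinted genes moved in both directions in KO iPSC against the WT pluripotent arrays. Of 26 measured genes 5 rose and 2 fell (6 and 5 adjusted over the list alone): the zinc finger gene Plagl1 (2.71), the IGF2 receptor Igf2r (1.36), Impact (1.31), the antisense transcript Kcnq1ot1 (1.22) and Dio3 (0.39) rose, and the adaptor Grb10 (-3.26) and the growth factor Igf2 (-1.08) fell (list adjusted p = 0.989). Of 21 primitive endoderm genes 2 rose and 2 fell (5 and 2 adjusted over the list alone), with the transcription factor Gata6 at 1.15 and the laminin Lamb1 at -2.14 (list adjusted p = 0.96). Of 18 trophectoderm genes 2 rose and 2 fell (3 and 4 adjusted over the list alone), with Tfap2a at least 11.6-fold higher and its relative Tfap2c at -1.53 (list adjusted p = 0.989). Of 16 LIF/STAT3 targets Stat3 (0.65) and Junb (0.45) rose and Bcl3 (-1.47), Noct (-0.84), Pim1 (-0.71) and Pim3 (-0.67) fell (4 and 4 adjusted over the list alone, list adjusted p = 0.886). Of 18 p53 and senescence genes Btg2 (0.82), the cell cycle inhibitor Cdkn1a (0.70) and Ei24 (0.41) rose and Zmat3 (-0.76) fell (3 and 1 adjusted over the list alone, list adjusted p = 0.25). Of 24 amino acid stress genes Cth (1.54), Ddit3 (1.20) and Slc7a11 (at least 1.18-fold) rose and Phgdh (-1.08), Aldh18a1 (-0.98) and Slc7a3 (-0.89) fell (4 and 5 adjusted over the list alone, list adjusted p = 0.998). Of 17 genes near Nanog on its chromosome 3 fell, Rimklb (-1.30), the glucose transporter Slc2a3 (-0.69) and Foxj2 (-0.56), and 0 rose, and these 3 fell adjusted over the list alone as well (list adjusted p = 0.406). Both MEF arrays lay above each WT pluripotent array in 2 of the 2 primitive endoderm genes that fell, Lamb1 and Dab2, in 1 of 2 trophectoderm, 1 of 2 imprinted, 2 of 3 amino acid stress and 1 of 3 neighbouring genes, so fibroblast RNA in the WT arrays was not excluded for these.

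Rlim stood at 7.02 and 6.83 in the KO iPSC arrays and between 10.34 and 11.06 in the other 5, KO MEF included. Rps13 stood at 6.67 and 5.67 in KO iPSC and 7.52 in KO MEF, and between 9.84 and 10.96 in the WT arrays. Xist, the RNA that coats the inactive X chromosome, stood at 11.97 in WT MEF, 9.65 and 7.96 in WT iPSC, 9.15 in KO MEF, 7.35 in WT ESC and 7.57 and 7.23 in KO iPSC. The Y-linked genes Eif2s3y and Uty stood at 9.21 and 8.78 in KO MEF and at no more than 6.25 in the other arrays. Dusp9, an X-linked ERK phosphatase chosen after its values were seen, stood at 11.91 and 11.69 in WT iPSC, 10.81 in WT ESC, 8.92 and 8.93 in KO iPSC, 9.43 in WT MEF and 7.99 in KO MEF.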
